A study of Mus musculus with 24 samples.

How the data were processed

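Skin RNA of 24 K6/ODC mice was hybridised, after biotin labelling of total RNA, to 24 Affymetrix Mouse 430 2.0 arrays, per the labels. The labels put 4 mice in each of 6 groups, which cross 2 diets with 3 doses of sodium arsenite in drinking water for 30 days. The folate-deficient diet was a purified AIN-76A type diet with succinyl sulfathiazole, and the sufficient diet held 5 mg/kg folic acid in addition, per the labels. Each array is a separate mouse, so the p-values measure the spread between mice.

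The authors deposited 1 table with an intensity for each of 45101 probe sets on each array. Per the submitters' processing notes GCOS and RMA were used, with versions not given in the sources used here. The deposited intensity values are linear and similar in scale between arrays (medians 36.3 to 39.4, upper quartiles 160 to 188, maxima 14491 to 16480), and how they were brought to that scale is not given in the sources used here. Probe sets were named through the platform annotation, of which 34945 had 1 gene symbol, 932 several and 9160 none, besides 64 controls. Entrez identifiers of 34741 matched the reference's gene table, which changed 0 symbols. Some genes of the lists and of the naming rule were not analysed here.

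The values were used as log2(value + 16), the form fixed for linear values, so fold changes are on that scale and understate the change of dim genes. Each of 18193 genes was represented by the probe set with the highest mean among those with 1 symbol, and 12511 genes were tested whose probe set was above the array's median on at least 4 arrays. A model of 6 group means was fitted with limma 3.58.1 in R 4.3.3 (18 residual and 4.44 prior degrees of freedom), and 12 contrasts were tested on both sides, with Benjamini-Hochberg adjustment within each contrast and a threshold of 0.05. Gene lists were tested with limma's camera at a preset correlation of 0.01, and again with an estimated correlation, adjusted over the lists of a contrast. Of 33 lists fixed beforehand with 919 genes, 713 of them tested, 32 had the minimum of 5 tested members, and erythroid cell and blood did not. A further list of sex-linked genes served as a check. Overlaps of calls were set beside the number that independent lists would share, only between contrasts with no mouse in common. Correlations of changes were set beside simulated unchanged groups and, for contrasts with the same unexposed mice, beside the values with the controls split. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.

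Genes were named by a rule. In a contrast with calls these were the 10 largest rises and 10 largest falls among called genes, and up to 3 members with the smallest p of each shifted list and always of the hair follicle, epidermal differentiation, one-carbon, NRF2 and metal lists. In a contrast without calls they were the 3 genes with the smallest p. Odc1, Krt6a, Krt6b, As3mt, Hmox1, Nqo1, Mt1, Mt2, Lor, Ivl, Flg, Krt1, Krt10 and the sex-linked genes were always given. The rule named 250 genes, of which the text prints those whose calls depended least on 1 array and some examples of the others. Of these 250, 116 had more than 1 probe set, and of 195 called pairs of gene and contrast, 15 had a probe set of opposite sign. Of the calls printed, these were Fn1 at 1 ppm (deficient diet and both diets), Lor at 1 ppm on the deficient diet, Cntn2 over all doses, Cd82 in the interaction at 1 ppm and Itga3 at 10 ppm over both diets, each with 1 such probe set. The transcripts of Krt6a and Krt6b are near-identical, so their probe sets may share signal.

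The groups, tests, lists, naming rule and a first set of alternatives were fixed before the data were examined. These alternatives were the replicate number as a block, no filter on dim genes, all probe sets, quantile normalization, array weights, scores of hair follicle, muscle and fat genes as covariates, only the compared groups in the fit, and each array left out in turn. A covariate for sex applied only if both sexes occurred. Added after the values were seen were a block for the 6 arrays with high hybridisation controls (1 per group, replicate 3 for the 10 ppm deficient group and replicate 1 for the others), the 18 other arrays alone, the 5'/3' ratio as a covariate, no pseudocount, the 2 arrays of lowest weight left out (replicate 4 of the unexposed and of the 10 ppm deficient group), and the 3 arrays with the lowest 5'/3' ratios left out (replicates 3 and 4 of the 1 ppm and replicate 1 of the 10 ppm deficient group). The 5'/3' ratio is the mean log2 ratio of the Gapdh and Actb control probe sets. Splits of the arrays into other groups were counted over all 35 splits of 2 groups, and over 100 drawn splits of more groups. They were counted again, after the values were seen, over splits that keep the 6 arrays even between the sides, 20 for 2 groups and 100 drawn for more. The permutation tests of the epidermis were likewise repeated over the 1600 splits of that kind within diets.

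The fit was tested on simulated data with 12511 genes, of which 200 changed, in 5 runs. For 10 ppm on the sufficient diet, 72.2% of genes changed by 0.5 on the log2 scale were recovered and 97.9% of those changed by 1, with 4.05% false calls. For the mean of both diets, the shares were 89.8% and 99.1% with 5.68% false calls, and for the interaction at 10 ppm 31.6% and 89% with 3.82% false calls. A list shifted by -0.3 was recovered in 10 of 10 runs with independent genes, and 0 lists were called without a shift. Exact permutation tests of 8 against 8 arrays ran over 12870 splits and were two-sided, and the permutation test of the clock score used 100000 resamples within doses. No pair of arrays held the same values (the smallest difference of 276 pairs was 0.0769), and every mouse was counted once.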

Results

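Gene expression was measured in mid-back skin of K6/ODC transgenic mice, in which an ornithine decarboxylase transgene is driven by a keratin 6 promoter. The mice drank water that held sodium arsenite at 0, 1 or 10 ppm for 30 days and ate a purified diet that was deficient in folate or held 5 mg/kg folic acid (sufficient). Each of the 6 groups held 4 mice with 1 array each, and 12511 genes were tested on the 24 arrays. The median intensity of an array lay between 36.3 and 39.4 and the upper quartile between 160 and 188. The number of arrays limits the precision, with a median standard error (SE) of 0.11 on the log2 scale for a difference between 2 groups and 0.15 for an interaction. All changes below are log2 changes ± SE from limma, with Benjamini-Hochberg adjusted p-values. In 6 arrays, 1 per group, the hybridisation controls (9.31 or more on the log2 scale, against 9.17 or less) and the upper quartile were above those of the other 18. Each count of genes is therefore also given with these 6 arrays as a block and within the 18 others, while the 6 alone, with 1 array per group, were not tested. The female-specific transcript Xist lay between 2264 and 4208 on all arrays, while Y-linked transcripts reached at most 13.3.

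The question of what 10 ppm arsenite did to the skin over both diets was addressed with the mean of the within-diet changes, 8 exposed against 8 unexposed mice. Transcripts of the outermost epidermal layers were lower in the exposed mice. The suprabasal keratin Krt1 was 2.15-fold lower (-1.10 ± 0.12, adjusted p = 7.03e-05), and lower in 8 of 8 exposed mice than in every unexposed mouse of their diet. In the same way, loricrin (Lor), the main protein of the cornified envelope, was 1.90-fold lower (-0.93 ± 0.11, adjusted p = 7.03e-05) and the cornification protease Casp14 was 2.11-fold lower (-1.08 ± 0.14, adjusted p = 9.11e-05), each in 8 of 8. The lipoxygenase Alox12b of the skin lipid barrier (-1.10 ± 0.15), the late envelope gene Lce1d (-0.87 ± 0.11), Psors1c2 (-0.81 ± 0.11), the histidine-degrading enzyme Hal (-0.999 ± 0.151), filaggrin (Flg, -0.93 ± 0.19), Krt10 (-0.60 ± 0.09) and involucrin (Ivl, -0.29 ± 0.06) fell too. The epithelial metallothionein Mt4 was 2.46-fold lower (-1.30 ± 0.25, adjusted p = 0.00447). Among the genes that rose were the monocyte chemokines Ccl7 (0.63 ± 0.12, adjusted p = 0.00346) and Ccl2 (0.44 ± 0.10, adjusted p = 0.0123), and the dendritic cell and macrophage lectins Clec4b1 (0.52 ± 0.09), Mgl2 (0.60 ± 0.14) and Cd209a (0.53 ± 0.12). The matrix genes Mfap5 (0.43 ± 0.08) and Fn1 (0.45 ± 0.11) and the mitotic kinase Bub1 (0.36 ± 0.08) rose as well, Fn1 without its call once the 3 arrays with the lowest 5'/3' ratios were left out. Single arrays stood apart in their group for Alox12b (replicate 3 of the 10 ppm deficient group, above the other 3), Mt4 (replicate 3 of the unexposed sufficient group, below) and Cd209a (replicate 4 of the unexposed deficient group, below). For Clec4b1 this held for replicate 4 of the unexposed sufficient group, below, and replicate 2 of the 10 ppm sufficient group, above.

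Of the 48 tested genes of the epidermal differentiation and cornified envelope list, 26 fell and 0 rose in this comparison (34 fell when adjusted over the list alone), with a median of -0.39. The list fell by limma's camera test (adjusted p = 2.04e-27; adjusted p = 0.0476 with an estimated correlation). That second value was 0.124 with the 6 arrays as a block, 0.0927 within the 18 others and 0.314 with tissue scores as covariates. The basal keratinocyte list moved the same way, with the hemidesmosome genes Col17a1 (-0.49 ± 0.07) and Itga3 (-0.45 ± 0.09) among 3 of 13 that fell (median -0.17, adjusted p = 0.000593; adjusted p = 0.516 with an estimated correlation). No other list kept its call with an estimated correlation. In the proliferation list 3 of 37 genes rose, Bub1 among them (8 over the list alone, adjusted p = 2.95e-08; adjusted p = 0.516 with an estimated correlation). In the fibroblast and matrix list 4 of 31 rose, Mfap5 and Fn1 among them (6 over the list alone, adjusted p = 6.66e-07; adjusted p = 0.548 with an estimated correlation). In the inflammatory list 4 of 21 rose and 0 fell, Ccl7 and Ccl2 among them (4 and 1 over the list alone, adjusted p = 0.00116; adjusted p = 0.516 with an estimated correlation). For Col17a1, replicate 4 of the 10 ppm sufficient group lay above the other 3.

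The camera test was passed by 7 further lists at 10 ppm, none of them with an estimated correlation. The myeloid list had 1 gene that rose (1 over the list alone, adjusted p = 0.000152; adjusted p = 0.693 with an estimated correlation), and so had the interferon response list (1 over the list alone, adjusted p = 0.000152; adjusted p = 0.693 with an estimated correlation). The immediate early genes had 3 that rose (5 over the list alone, adjusted p = 0.00745; adjusted p = 0.693 with an estimated correlation). The mast cell list had 0 (1 over the list alone, adjusted p = 0.0102; adjusted p = 0.693 with an estimated correlation) and the endothelium list 1 (1 over the list alone, adjusted p = 0.0102; adjusted p = 0.537 with an estimated correlation). In the oxidative phosphorylation list 2 rose and 1 fell (2 and 1 over the list alone, adjusted p = 0.0102; adjusted p = 0.693 with an estimated correlation). In the heat shock list 2 rose (5 over the list alone, adjusted p = 0.0353; adjusted p = 0.693 with an estimated correlation). The NRF2 and oxidative stress list (adjusted p = 0.927), the metal and arsenic handling list (0.704; 2 genes fell, Mt4 among them), the one-carbon and folate list (0.941), the unfolded protein list (0.941) and the p53 targets (0.859) did not pass. Of genes often studied with arsenic, Hmox1 (0.08 ± 0.11, adjusted p = 0.772), Nqo1 (-0.07 ± 0.07, 0.618), Mt1 (0.00 ± 0.08, 0.989), Mt2 (0.18 ± 0.09, 0.259) and the arsenic methyltransferase As3mt (0.09 ± 0.08, 0.612) did not pass either. Odc1 (0.15 ± 0.06, 0.133), with 2 of its 3 probe sets of opposite sign, and the hyperproliferation keratins Krt6a (0.00 ± 0.05, 0.988) and Krt6b (0.08 ± 0.19, 0.877) were likewise not past the threshold. For Mt1, replicate 1 of the unexposed sufficient group lay below the other 3.

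Beyond these, the camera test at 10 ppm over both diets did not pass for ribosomal proteins (adjusted p = 0.275), growing hair follicle (0.303; 3 genes fell), circadian clock (0.377; 2 fell), adipocyte (0.423; 2 fell), cholesterol and fatty acid synthesis (0.423), hyperproliferative epidermis (0.433; 1 fell) or glucocorticoid targets (0.563). It did not pass either for sebaceous gland (0.704; 1 fell), lymphocyte (0.704), DNA repair (0.751), DNA and histone methylation (0.766; 1 fell), skeletal muscle (0.887), Schwann cell (0.902; 1 fell), polyamine metabolism (0.902) and melanocyte (0.927). The median and the test differed in sign for skeletal muscle, whose median was -0.01 with a test direction upward. Of all genes, 174 rose and 508 fell, 682 in all, of which 7 changed by more than 2-fold, while 2560 had an unadjusted p under 0.05. The count was 1107 with the 6 arrays as a block and 550 within the 18 others. It was 422 without replicate 4 of the unexposed sufficient group, 435 without replicate 4 of the unexposed deficient group and 447 without replicate 1 of the 10 ppm deficient group.

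**Figure D1:**
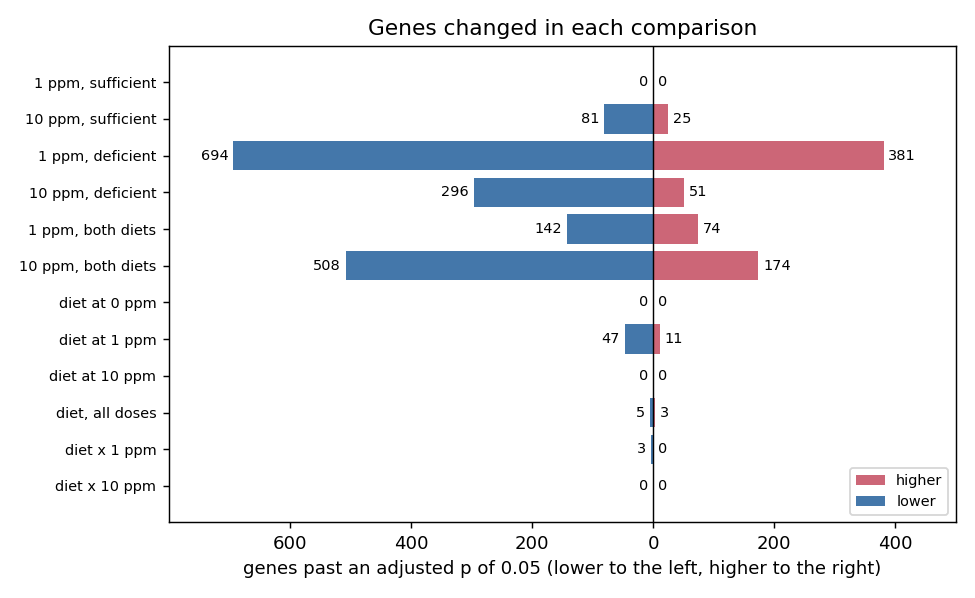
Horizontal bars give the number of genes past the limma threshold in each of the 12 comparisons, lower genes to the left and higher genes to the right. The longest bars belong to 1 ppm on the deficient diet, with 694 lower and 381 higher genes, and to 10 ppm over both diets, with 508 lower and 174 higher genes.

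On the folate-sufficient diet alone, 10 ppm arsenite was compared with 0 ppm in 4 against 4 mice. Krt1 was 2.38-fold lower (-1.25 ± 0.17, adjusted p = 0.00199), Casp14 2.39-fold lower (-1.26 ± 0.19, adjusted p = 0.00482), the thioesterase Them5 2.21-fold lower (-1.14 ± 0.16, adjusted p = 0.00199), Lce1d 1.97-fold lower (-0.98 ± 0.15, adjusted p = 0.00482) and Psors1c2 1.88-fold lower (-0.91 ± 0.15, adjusted p = 0.00705), each in 4 of 4 mice below every unexposed mouse. Albumin (Alb), the main plasma protein made by the liver, was lower (adjusted p = 0.00705, and 0.0414 without replicate 4 of the unexposed group), since the 4 unexposed arrays held 415, 756, 537 and 5492 and the 10 ppm group a mean of 33.9 ± 4.71 (SD, n = 4), which lies below the lowest array median of 36.3, so that no size of change is given. The liver serpin Serpina1c (adjusted p = 0.0201, and 0.0414 without replicate 4 of the unexposed group) stood with it, also below that median at 10 ppm (14.5 ± 1.15, SD, n = 4), and both were highest on replicate 4 of the unexposed group. Without replicate 1, 2 or 4 of the 10 ppm group, or with only these 2 groups in the fit, Serpina1c was not past the threshold (adjusted p from 0.0531 to 0.0714 in the former case).

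Several genes were higher on the sufficient diet at 10 ppm, each with a call that 1 array could end. The immediate early gene Fos was 2.57-fold higher (1.36 ± 0.29, adjusted p = 0.0276). Its adjusted p lay between 0.0531 and 0.101 without replicates 1 or 2 of the unexposed or 1, 2 or 4 of the 10 ppm group. The interferon-induced chemokine Cxcl10 was higher by 0.48 ± 0.10 (adjusted p = 0.0268; 0.0624 to 0.105 without replicate 1 of the unexposed or 1, 2 or 4 of the 10 ppm group). The endothelial factor Klf2 was higher by 0.55 ± 0.10 (adjusted p = 0.0139; 0.0501 to 0.0662 without replicate 4 of the unexposed or 1 or 4 of the 10 ppm group). The calls of Fos, Cxcl10 and Klf2 also ended within the 18 arrays. Hal fell by 1.17 ± 0.21 (adjusted p = 0.0115; 0.0512 without replicate 4 of the unexposed and 0.057 without replicate 1 of the 10 ppm group).

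In the cornified envelope list 16 of 48 genes fell and 0 rose on the sufficient diet (34 over the list alone, median -0.49; camera adjusted p = 3.78e-42; adjusted p = 0.00632 with an estimated correlation). That call also held with the 6 arrays as a block (0.0207) and within the 18 others (0.0194), but not with tissue scores as covariates (0.0527). In the interferon response list 3 of 29 rose, Cxcl10 among them (11 over the list alone, adjusted p = 4.18e-13; adjusted p = 0.252 with an estimated correlation). In the immediate early list 3 of 20 rose, Fos and Klf2 among them (7 over the list alone, adjusted p = 6.27e-07; adjusted p = 0.288 with an estimated correlation). The fibroblast and matrix list (median 0.23, adjusted p = 1.29e-10; adjusted p = 0.288 with an estimated correlation), the myeloid list (median 0.30, adjusted p = 4.12e-10; adjusted p = 0.304 with an estimated correlation) and the proliferation list (median 0.17, adjusted p = 2.3e-09; adjusted p = 0.292 with an estimated correlation) were shifted upward with 0 genes past the threshold over all genes. In the inflammatory list 2 rose and 1 fell (5 and 2 over the list alone, adjusted p = 0.0059; adjusted p = 0.304 with an estimated correlation). The basal keratinocyte list was lower too, with Col17a1 (-0.44 ± 0.10, adjusted p = 0.0356) the 1 gene that fell (median -0.16, adjusted p = 6.49e-05; adjusted p = 0.252 with an estimated correlation). The call of Col17a1 ended in 7 of the 8 refits without 1 array (adjusted p up to 0.134). Lower as well were the hyperproliferative epidermis list (median -0.17, adjusted p = 0.000519; adjusted p = 0.367 with an estimated correlation) and the hair follicle list (median -0.06, adjusted p = 0.0165; adjusted p = 0.304 with an estimated correlation). The mast cell (median 0.24, adjusted p = 0.0112), endothelium (median 0.10, adjusted p = 0.0112) and oxidative phosphorylation lists (median 0.06, adjusted p = 0.0138) were higher. With an estimated correlation the adjusted p of these 3 lists was 0.609, 0.304 and 0.559. In all, 13 lists were shifted, and the cornified envelope list alone kept its call with an estimated correlation.

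Over all genes at 10 ppm on the sufficient diet, 25 rose and 81 fell, 106 in all, 16 of them by more than 2-fold. The count was 164 with the 6 arrays as a block and 41 within the 18 others. It was 54, 56 and 24 without replicates 1, 3 and 4 of the unexposed group, and 11, 35, 66 and 32 without replicates 1, 2, 3 and 4 of the 10 ppm group. Of 27 called genes named by rule, 6 kept their call in all 8 refits, and these were Krt1, Them5, Casp14, Lce1d, Psors1c2 and Alb.

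**Figure D2:**
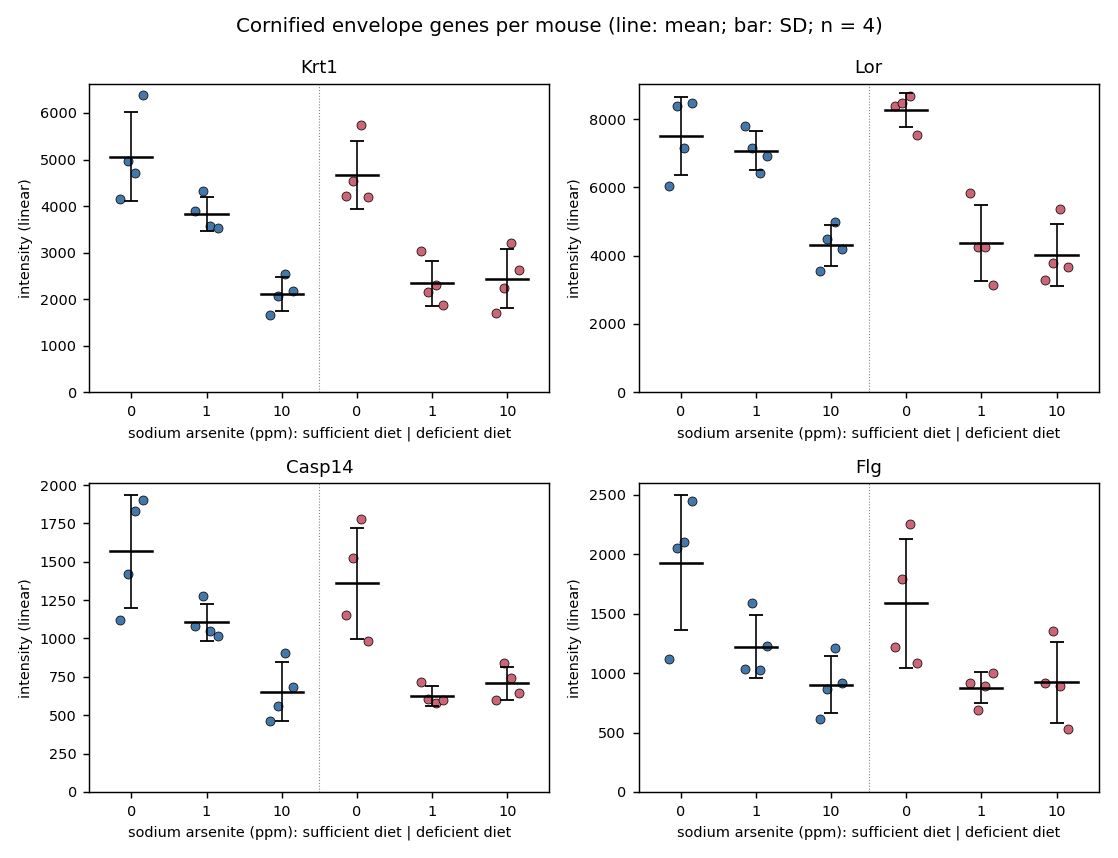
Each point is the deposited intensity of Krt1, Lor, Casp14 or Flg in 1 mouse on a linear axis, by arsenite dose, with blue for the sufficient and red for the deficient diet, a line at the mean of 4 mice and a bar for the SD. Krt1 averaged 5057 and 4668 in the unexposed sufficient and deficient groups and 2110 and 2442 at 10 ppm.

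On the folate-deficient diet, 10 ppm arsenite was again compared with 0 ppm in 4 against 4 mice. Lor was 2.08-fold lower (-1.06 ± 0.16, adjusted p = 0.00381), Alox12b 2.20-fold lower (-1.14 ± 0.21, adjusted p = 0.00817) and Krt1 1.94-fold lower (-0.96 ± 0.17, adjusted p = 0.00817), each in 4 of 4 mice below every unexposed mouse. The calcium-binding protein Tesc (-0.90 ± 0.15), the membrane protein Susd2 (-0.86 ± 0.14) and Fndc9 (-0.93 ± 0.15) fell as well, each with an adjusted p of 0.00381. The golgi protein Ergic2 rose by 0.75 ± 0.17 (adjusted p = 0.0196; 0.0571 without replicate 4 of the unexposed group). Casp14 fell by 0.90 ± 0.19 (adjusted p = 0.017; 0.0565 without replicate 3 of the unexposed and 0.0516 without replicate 1 of the 10 ppm group). Of these genes, Fndc9 alone kept its call with only these 2 groups in the fit. In the 10 ppm group replicate 3 lay above the other 3 for Alox12b.

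In the cornified envelope list 12 of 48 genes fell and 0 rose on the deficient diet (23 over the list alone, median -0.31; camera adjusted p = 6.28e-10; adjusted p = 0.969 with an estimated correlation). The proliferation list had 1 gene that rose (1 over the list alone, adjusted p = 0.000774), the heat shock list 0 (2 over the list alone, adjusted p = 0.0127), the inflammatory list 1 (adjusted p = 0.0232) and the fibroblast and matrix list 1 (adjusted p = 0.0437). With an estimated correlation the adjusted p was 0.969 for each of these lists. The count of 5 shifted lists was 3 without replicate 2 and 8 without replicate 4 of the unexposed group.

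Over all genes at 10 ppm on the deficient diet, 51 rose and 296 fell, 347 in all, 4 of them by more than 2-fold. After quantile normalization 99 rose and 217 fell. The count was 734 with the 6 arrays as a block and 238 within the 18 others. It was 217, 149 and 86 without replicates 2, 3 and 4 of the unexposed group, and 141 and 221 without replicates 1 and 4 of the 10 ppm group. With only these 2 groups in the fit the count was 1, where the log2 changes were the same by construction and the median SE of the 347 genes went from 0.0926 to 0.104. The limma array weights were lowest for replicate 4 of the 10 ppm group (0.139) and replicate 4 of the unexposed group (0.319), and without these 2 arrays the count was 39.

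The lower genes of both diets at 10 ppm, which come from different mice, were compared directly. Of the 81 genes that fell on the sufficient and the 296 that fell on the deficient diet, 40 were shared, Krt1 and Casp14 among them, where 1.92 would be shared between independent lists. Of the higher genes, 1 was shared, against 0.10. The log2 changes correlated across the 12511 genes with r = 0.34, against 0.00 in simulated unchanged groups, though genes are not independent replicates.

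The interaction of diet and 10 ppm arsenite asked whether the change differed between the diets. No gene passed limma's threshold (0, with 817 at an unadjusted p under 0.05). Array weights gave 4 genes and tissue scores as covariates 1, while the count was 0 with the 6 arrays as a block and 0 within the 18 others. The smallest p-values were those of Cxcl10 (-0.76 ± 0.14, adjusted p = 0.151), the branched-chain aminotransferase Bcat2 (-0.64 ± 0.12, adjusted p = 0.151) and the guanylate-binding protein Gbp2 (-0.88 ± 0.19, adjusted p = 0.407). The interferon response list was the list with the smallest p (median -0.31; 0 genes past the threshold and 5 lower over the list alone, camera adjusted p = 1.7e-08; adjusted p = 0.766 with an estimated correlation). The cornified envelope list (median 0.09, adjusted p = 2.41e-06), the hyperproliferative epidermis list (median 0.19, adjusted p = 5.34e-05) and the immediate early list (median -0.31, adjusted p = 9.75e-05) each had adjusted p = 0.766 with an estimated correlation. The myeloid list (median -0.29, adjusted p = 8.32e-05), the fibroblast and matrix list (median -0.13, adjusted p = 0.0272) and the heat shock list (median 0.06, adjusted p = 0.0325) each had adjusted p = 0.989 with an estimated correlation. Replicate 2 of the unexposed sufficient group lay above the other 3 for Gbp2.

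The effect of 1 ppm arsenite over both diets was taken from 8 exposed against 8 unexposed mice. Fibronectin (Fn1), a matrix glycoprotein, was 1.60-fold higher (0.67 ± 0.11, adjusted p = 0.011), the lectin Cd209a rose by 0.64 ± 0.12 (adjusted p = 0.0139) and the cytochrome Cyp1b1 by 0.62 ± 0.11 (adjusted p = 0.0114), each above the unexposed mean of its diet in 8 of 8 mice. Krt1 was 1.62-fold lower (-0.70 ± 0.12, adjusted p = 0.011), Casp14 1.71-fold lower (-0.77 ± 0.14, adjusted p = 0.011), and Psors1c2 fell by 0.72 ± 0.11 (adjusted p = 0.00728), each below that mean in 8 of 8. The cornified envelope precursor Sprr2d fell by 1.38 ± 0.25, its relative Sprr2h by 1.04 ± 0.19 (adjusted p = 0.011 each) and the methyltransferase Inmt by 1.02 ± 0.16 (adjusted p = 0.011), each below that mean in 8 of 8. All of these calls, like all 216 of the comparison, ended with tissue scores as covariates and without the 3 arrays with the lowest 5'/3' ratios. In the first case the median of the 216 genes kept 77.7% of the change while the median SE went from 0.0881 to 0.109. In the second it kept 96.5% with an SE of 0.0954. Fn1 was lower on replicate 2 of the 1 ppm sufficient group than on the other 3, Cd209a lower on replicate 4 of the unexposed deficient group, and Sprr2d higher on replicate 1 of the 1 ppm deficient group.

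In the cornified envelope list 19 of 48 genes fell and 0 rose at 1 ppm over both diets (33 over the list alone, median -0.34; camera adjusted p = 1.46e-27; adjusted p = 0.0466 with an estimated correlation). That second value was 0.115 with the 6 arrays as a block, 0.0643 within the 18 others and 0.37 with tissue scores as covariates. In the skeletal muscle list 3 of 37 fell (31 over the list alone, median -0.91; adjusted p = 1.68e-17; adjusted p = 0.549 with an estimated correlation). Its level differed between mice of 1 group, from -2.39 to 0.12 in the 1 ppm sufficient group relative to the unexposed sufficient mean. In the mast cell list 2 of 9 rose (6 over the list alone, median 0.46; adjusted p = 9.46e-07; adjusted p = 0.549 with an estimated correlation). In the fibroblast and matrix list 1 rose, Fn1 (9 over the list alone, adjusted p = 2.3e-06; adjusted p = 0.564 with an estimated correlation). The proliferation list had 0 past the threshold over all genes (7 rose over the list alone, adjusted p = 7.78e-07; adjusted p = 0.564 with an estimated correlation). In the hyperproliferative epidermis list 1 fell (7 over the list alone, adjusted p = 1.09e-05; adjusted p = 0.549 with an estimated correlation). The myeloid list (adjusted p = 5.71e-05; adjusted p = 0.701 with an estimated correlation), the interferon response list (0.000175; adjusted p = 0.645 with an estimated correlation), the basal keratinocyte and inflammatory lists (0.0367 each; adjusted p = 0.609 with an estimated correlation) and the hair follicle list (0.0367, 1 gene fell; adjusted p = 0.564 with an estimated correlation) completed the 11 that were shifted.

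Over all genes at 1 ppm over both diets, 74 rose and 142 fell, 216 in all, 7 of them by more than 2-fold. The count was 534 with the 6 arrays as a block and 199 within the 18 others. It was 85 and 56 without replicates 3 and 4 of the unexposed sufficient group, and 340, 132, 105 and 70 without replicates 1 to 4 of the unexposed deficient group. It was 105, 473, 47 and 49 without replicates 1 to 4 of the 1 ppm sufficient group, and 575, 51 and 100 without replicates 1, 2 and 4 of the 1 ppm deficient group.

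**Figure D3:**
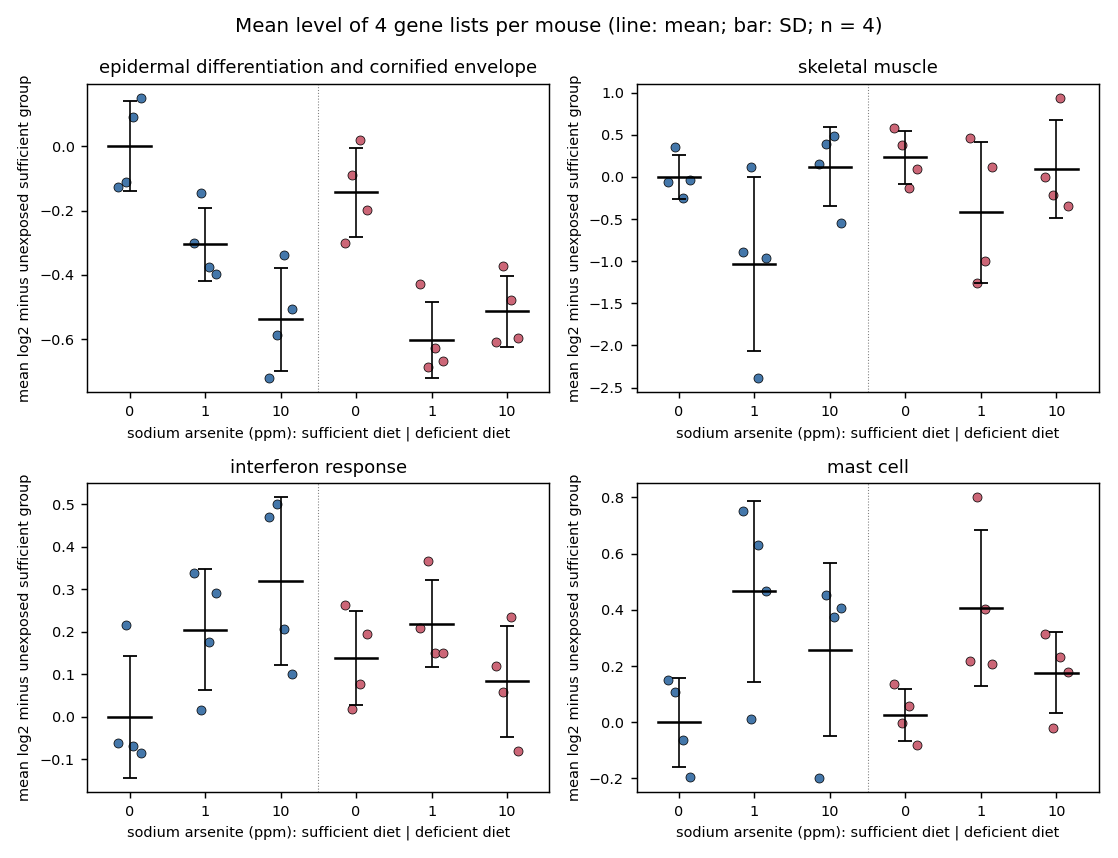
Each point is the mean log2 level of 1 gene list in 1 mouse minus the mean of the unexposed sufficient group, for epidermal differentiation, skeletal muscle, interferon response and mast cell genes, by dose and diet. The epidermal differentiation list averaged -0.54 at 10 ppm on the sufficient and -0.60 at 1 ppm on the deficient diet, while the muscle list at 1 ppm on the sufficient diet spread from -2.39 to 0.12.

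On the folate-sufficient diet alone, no gene passed limma's threshold at 1 ppm (0, with 975 at an unadjusted p under 0.05). The count was 0 with the 6 arrays as a block, 1 within the 18 others and 695 with array weights. It was 20, 2, 1 and 35 without replicates 2 and 3 of the unexposed and 1 and 2 of the 1 ppm group, and 191 with replicate 2 of these groups exchanged, so the count of 0 depends on these samples. The smallest p-values were those of the serpin Serpinb12 (-1.23 ± 0.22), Inmt (-1.21 ± 0.23) and Sprr2d (-1.78 ± 0.35), all with an adjusted p of 0.127. Of the 10 lists past the camera test, none passed with an estimated correlation. The skeletal muscle list had the smallest p, with 0 of 37 past the threshold over all genes and 26 lower over the list alone (median -1.14; adjusted p = 2.48e-29; adjusted p = 0.192 with an estimated correlation). The cornified envelope list had 12 lower over the list alone (median -0.20; adjusted p = 3.71e-20; adjusted p = 0.0886 with an estimated correlation) and the mast cell list 8 of 9 higher over the list alone (median 0.42; adjusted p = 1.18e-08; adjusted p = 0.192 with an estimated correlation).

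On the folate-deficient diet alone, 1 ppm was compared with 0 ppm in 4 against 4 mice. Krt1 was 2.00-fold lower (-1.002 ± 0.174, adjusted p = 0.00381), Casp14 2.09-fold lower (-1.07 ± 0.19, adjusted p = 0.00429), and Lor (-0.95 ± 0.16, adjusted p = 0.00308), Alox12b (-0.96 ± 0.21), Psors1c2 (-0.97 ± 0.15) and Tlcd3b (-1.09 ± 0.17) fell, each in 4 of 4 mice below every unexposed mouse. Cd209a was 1.86-fold higher (0.90 ± 0.18, adjusted p = 0.00611) and Fn1 1.69-fold higher (0.76 ± 0.16, adjusted p = 0.00896), in 4 of 4 above every unexposed mouse. The immunoglobulin joining chain Jchain was 2.44-fold higher (1.29 ± 0.33, adjusted p = 0.0214; 0.0505 to 0.104 without replicate 4 of the unexposed or 3 or 4 of the 1 ppm group). The mast cell protease Cpa3 rose by 0.87 ± 0.24 (adjusted p = 0.0298; 0.0538 to 0.127 without replicate 3 or 4 of the unexposed or 2 or 4 of the 1 ppm group). Of these genes, Lor, Alox12b, Psors1c2 and Tlcd3b kept their calls with tissue scores as covariates, and none did with only these 2 groups in the fit. Cd209a was lower on replicate 4 of the unexposed group than on the other 3.

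In the cornified envelope list 21 of 48 genes fell and 0 rose at 1 ppm on the deficient diet (33 over the list alone, median -0.40; camera adjusted p = 3.4e-16; adjusted p = 0.326 with an estimated correlation). The proliferation list had 4 that rose (4 over the list alone, adjusted p = 5.52e-05), the mast cell list 2, Cpa3 among them (3 over the list alone, adjusted p = 0.0121), the heat shock list 3 (3 over the list alone, adjusted p = 0.0337) and the inflammatory list 0 (adjusted p = 0.0487). Each of these 4 lists had adjusted p = 0.986 with an estimated correlation. In the skeletal muscle list 1 fell (0 over the list alone, median -0.65; adjusted p = 0.000254; adjusted p = 0.986 with an estimated correlation). The count of 6 shifted lists was 3 without replicate 2 of the 1 ppm group. Relative to the unexposed deficient group, the tissue scores of the 1 ppm deficient group were -0.415 for hair follicle, -0.824 for muscle and -0.0965 for fat. The log2 5'/3' ratio of Gapdh and Actb, a measure of RNA integrity, averaged -1.54 ± 0.56 (SD, n = 4) in the 1 ppm deficient group and -1.03 ± 0.31 (SD, n = 4) in its unexposed group.

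Over all genes at 1 ppm on the deficient diet, 381 rose and 694 fell, 1075 in all, 8 of them by more than 2-fold. The count was 1728 with the 6 arrays as a block and 1336 within the 18 others. It was 689 and 190 without replicates 3 and 4 of the unexposed group, and 430 and 306 without replicates 2 and 4 of the 1 ppm group. It was 80 with tissue scores as covariates, 3 with only these 2 groups in the fit, 367 without the 2 arrays of lowest weight, and 161 without the 3 arrays with the lowest 5'/3' ratios, 2 of which are in this group.

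The changes at 1 and 10 ppm on the deficient diet share their unexposed mice. The correlation across genes was 0.77, against 0.50 in simulated unchanged groups that share controls, and 0.51 (0.47 to 0.58) when the controls were split. The covariance was 0.0314 against a simulated 0.00845. On the sufficient diet the correlation was 0.62, against a simulated 0.50, and 0.31 (0.21 to 0.38) with split controls, with a covariance of 0.0198 against 0.00843.

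The interaction of diet and 1 ppm arsenite gave 3 genes, all lower in the deficient diet's change. These were Bcat2 (-0.83 ± 0.12, adjusted p = 0.00895), the membrane protein Cd82 (-0.83 ± 0.13, adjusted p = 0.0155) and the phospholipase Pla2g2e (-0.67 ± 0.12, adjusted p = 0.0323). The call of Bcat2 held in all 16 refits without 1 array, but ended after quantile normalization, within the 18 arrays and with only the compared groups in the fit (adjusted p up to 0.106). Those of Cd82 and Pla2g2e also ended within the 18 arrays, with only the compared groups and without the 3 arrays with the lowest 5'/3' ratios, and that of Pla2g2e after quantile normalization and with tissue scores as covariates. The call of Cd82 ended without replicates 3 or 4 of the unexposed deficient or 3 of the 1 ppm sufficient group (adjusted p from 0.055 to 0.0629). That of Pla2g2e ended without 10 of the 16 arrays (0.0504 to 0.127), which were replicates 2, 3 and 4 of both unexposed groups, 1 and 3 of the 1 ppm sufficient and 2 and 4 of the 1 ppm deficient group. The count was 18 with the 6 arrays as a block and 0 within the 18 others. On all arrays 1808 genes had an unadjusted p under 0.05. It was 1 without replicate 3 or 4 of the unexposed deficient or 3 of the 1 ppm sufficient group, and 5 and 8 without replicates 1 and 3 of the 1 ppm deficient group. The hyperproliferative epidermis list was the 1 list that shifted (median 0.29; camera adjusted p = 0.0286; adjusted p = 0.904 with an estimated correlation). The number of lists was 2 without replicate 4 of the unexposed sufficient, 1 of the unexposed deficient or 1 or 3 of the 1 ppm sufficient group, and 3 without replicate 3 of the unexposed sufficient, 4 of the 1 ppm sufficient or 1 of the 1 ppm deficient group. It was 4 without replicate 1 of the unexposed sufficient or 2 of the unexposed deficient group, and 5 without replicate 2 of the unexposed sufficient, 4 of the unexposed deficient, 2 of the 1 ppm sufficient or 2 of the 1 ppm deficient group.

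The diets were compared over all doses in 12 deficient against 12 sufficient mice. The clock repressor Nr1d1 was 1.34-fold lower on the deficient diet (-0.42 ± 0.06, adjusted p = 0.0049), below the sufficient mean of its dose in 11 of 12 mice, and Ivl was 1.24-fold lower (-0.31 ± 0.05, adjusted p = 0.0049) in 12 of 12. The lipolysis inhibitor G0s2 was 1.54-fold higher (0.62 ± 0.10, adjusted p = 0.0144), Cntn2 rose by 0.29 ± 0.05 and Smim5 fell by 0.26 ± 0.04 (adjusted p = 0.0144 each), all in 12 of 12. In unexposed mice Nr1d1 hardly differed (-0.10 ± 0.11, adjusted p = 0.834), so its mean rests on the 1 and 10 ppm groups. These 5 genes kept their calls in all 24 refits without 1 array, and each lost it within the 18 arrays. Cntn2, G0s2 and Smim5 also lost it without the 3 arrays with the lowest 5'/3' ratios. The other 3 genes were Foxq1 (-0.33 ± 0.06, adjusted p = 0.0473), Rrp1b (0.23 ± 0.04, adjusted p = 0.0498) and Map3k8 (-0.33 ± 0.06, adjusted p = 0.0498), whose calls ended in 16, 21 and 19 of the 24 refits. Single arrays stood apart for Nr1d1 (replicate 4 of the 10 ppm sufficient group, below the other 3), G0s2 (replicate 2 of the unexposed sufficient group, above) and Map3k8 (replicate 4 of the 10 ppm deficient group, below).

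The one-carbon and folate list did not pass for the diet (camera adjusted p = 0.324), with 0 genes past the threshold and 3 higher over the list alone. Its smallest p-values were those of the mitochondrial formate enzyme Mthfd1l (0.28 ± 0.06, adjusted p = 0.115), the serine hydroxymethyltransferase Shmt1 (0.18 ± 0.05, 0.223) and Mthfd2 (0.19 ± 0.06, 0.265). The cornified envelope list had 1 gene that fell, Ivl (3 over the list alone, median -0.11; adjusted p = 3.72e-11; adjusted p = 0.912 with an estimated correlation). The skeletal muscle list (median 0.26; adjusted p = 0.000106; adjusted p = 0.957 with an estimated correlation), the heat shock list (3 higher over the list alone, adjusted p = 0.000242; adjusted p = 0.933 with an estimated correlation) and the proliferation list (2 higher over the list alone, adjusted p = 0.000457; adjusted p = 0.933 with an estimated correlation) were shifted upward. The diet changes of Krt1 (-0.21 ± 0.10, adjusted p = 0.526), Lor (-0.23 ± 0.09, 0.436), Mt2 (0.26 ± 0.07, 0.186) and Odc1 (0.12 ± 0.05, 0.417) did not pass. The total of 3 higher and 5 lower genes, 8 in all, became 6 and 5 after quantile normalization, with 1149 at an unadjusted p under 0.05. It was 14 with the 6 arrays as a block and 0 within the 18 others. It was 5 without replicates 1, 3 or 4 of the unexposed sufficient, 2 of the unexposed deficient, 3 of the 1 ppm sufficient, 1, 3 or 4 of the 1 ppm deficient, 1 or 3 of the 10 ppm sufficient and 1 or 4 of the 10 ppm deficient group. It was 17 without replicate 2 of the 1 ppm deficient group. Replicate 3 of the 10 ppm deficient group lay above the other 3 for Shmt1, and replicate 2 of the 10 ppm sufficient group below them for Mthfd2.

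At 1 ppm alone, 58 genes differed between the diets in 4 against 4 mice, 11 higher and 47 lower on the deficient diet, with 1685 at an unadjusted p under 0.05. Nr1d1 was 1.66-fold lower (-0.73 ± 0.11, adjusted p = 0.00826), Ivl fell by 0.48 ± 0.08 (adjusted p = 0.0131) and the retinoic acid hydroxylase Cyp26a1 rose by 0.62 ± 0.10 (adjusted p = 0.0131), each in 4 of 4 mice beyond every sufficient mouse. All 3 calls ended without replicate 1 of the sufficient or 4 of the deficient group, with adjusted p from 0.059 to 0.0665 for Nr1d1, 0.077 to 0.0818 for Ivl and 0.0629 to 0.0818 for Cyp26a1. They also ended with only these 2 groups in the fit, where the count was 0, and without the 3 arrays with the lowest 5'/3' ratios, where it was 0 as well. In the former case the log2 changes were the same by construction and the median SE of the 58 genes went from 0.0907 to 0.0921. In the latter the median gene kept 92.3% (quartiles 79.6 to 101) of its change with an SE of 0.104. The log2 5'/3' ratio itself differed between these groups, with -1.54 ± 0.56 (SD, n = 4) on the deficient and -1.08 ± 0.17 (SD, n = 4) on the sufficient diet. With tissue scores as covariates 10 of the 58 calls held, at a median of 93.1% of the change and an SE of 0.0943. The cornified envelope list had 4 genes that fell, Ivl among them (16 over the list alone, median -0.28; camera adjusted p = 4.49e-14; adjusted p = 0.494 with an estimated correlation). The muscle list (median 0.64; adjusted p = 3.81e-06), the proliferation list (median 0.11; adjusted p = 3.47e-05) and the heat shock list (median 0.16; adjusted p = 0.00089) each had adjusted p = 0.961 with an estimated correlation. The 4 shifted lists became 7 without replicate 2 of the deficient group. The gene count was 119 with the 6 arrays as a block and 32 within the 18 others, where the call of Cyp26a1 ended too. It was 0, 8, 3 and 10 without replicates 1 to 4 of the sufficient group, and 152, 18 and 0 without replicates 1, 2 and 4 of the deficient group.

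In unexposed mice, no gene differed between the diets by limma (0, with 1004 at an unadjusted p under 0.05). The count was 0 with the 6 arrays as a block, 1 within the 18 others and 54 with array weights. The smallest p-values were those of Alb (lower, adjusted p = 0.112), Serpina1c (lower, adjusted p = 0.229) and Bcat2 (0.42 ± 0.09, adjusted p = 0.229). Of 4 shifted lists, none held with an estimated correlation (adjusted p = 0.945 for each). The cornified envelope list was lower (median -0.09, camera adjusted p = 2.94e-06), the hyperproliferative epidermis list lower (median -0.15, adjusted p = 0.00986), and the interferon response (median 0.14, adjusted p = 0.0156) and immediate early lists (median 0.17, adjusted p = 0.0367) higher. The number of lists was 2 without replicate 1 of the sufficient group, and 0 and 7 without replicates 1 and 4 of the deficient group. In the deficient group Alb (40.0 ± 8.41, SD, n = 4) and Serpina1c (15.81 ± 1.495, SD, n = 4) were near or below the array medians, so no size of change is given. Replicate 3 of the deficient group lay above the other 3 for Serpina1c.

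At 10 ppm, no gene differed between the diets either (0, with 561 at an unadjusted p under 0.05), and the count was 0 with the 6 arrays as a block, within the 18 others and in all other settings. The smallest p-values were those of Thbs4 (0.57 ± 0.14), Nr1d1 (-0.44 ± 0.11) and Gpr83 (0.32 ± 0.08), all with an adjusted p of 0.871. The interferon response list was lower on the deficient diet (median -0.23; 3 lower over the list alone, camera adjusted p = 9.06e-08), as were the myeloid (median -0.17; adjusted p = 0.000686) and immediate early lists (median -0.13; adjusted p = 0.00729). With an estimated correlation each of these 3, like the 2 that were higher, had adjusted p = 0.983. The latter were the heat shock (median 0.11; adjusted p = 0.00132) and hyperproliferative epidermis lists (median 0.12; adjusted p = 0.0174). The 5 shifted lists became 3 without replicate 1 or 2 of the sufficient group. Replicate 4 of the sufficient group lay below the other 3 for Nr1d1.

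**Figure D4:**
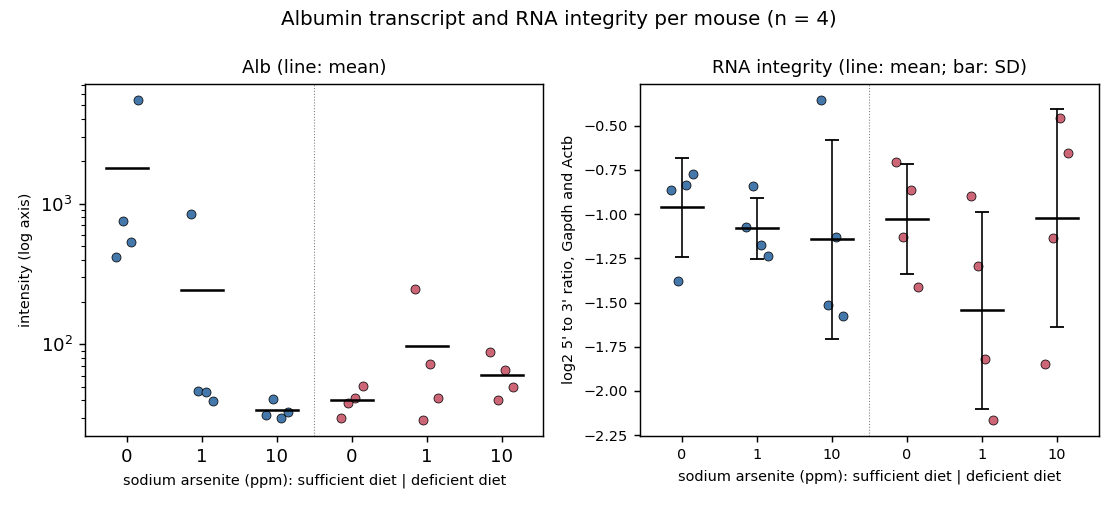
The panels show the deposited intensity of Alb on a log axis and the log2 5'/3' ratio of Gapdh and Actb, 1 point per mouse by group. Alb was highest in the unexposed sufficient group, with 5492 on 1 array, and the 5'/3' ratio averaged -1.54 in the 1 ppm deficient group.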

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

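The tests of liver RNA, of tissue makeup, of RNA integrity, of the 6 arrays with high hybridisation controls and of the epidermis share, the splits and permutations that keep the 6 arrays even between the sides, like the fits without the arrays of low 5'/3' ratio or low weight, were chosen only after the result they bear on was seen. Chance alone sets 1 array apart in about 1 in 20 groups of 4, and 68 of the 1202 groups tested held such an array.

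Transcripts of liver genes were high on the 4 unexposed sufficient arrays, and highest on replicate 4, where Alb reached 5492 and the others 415, 756 and 537. A response of the skin to diet or arsenite was argued against by the spread of 3.68 on the log2 scale among the 4 mice, which received the same treatment, and by 1 array outside the group (replicate 1 of the 1 ppm sufficient group, 840) with Alb at or above their lowest. That spread rests on replicate 4, so for the other 3 a response stays open. RNA of liver in these samples is a candidate source, since 21 liver genes not looked at before had a median difference of 0.832 (0.669 to 1.2, bootstrap over genes) and 19 of them were highest on replicate 4, with Apob (-0.04) and Hp (-0.49) not higher. The median rests mostly on replicate 4, where it was 2.77, against 0.286 (0.176 to 0.447) on the other 3, an interval that leaves these 3 undecided. Where it entered was not tested, and no biological explanation other than the treatments was.

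The 1075 genes at 1 ppm on the deficient diet varied widely between settings. From slopes within the other 4 groups, RNA integrity predicted a median 0.103 (0.0868 to 0.121) of their change, with the same sign for 73.8%. Another share of hair follicle, muscle or fat predicted 0.0908 (0.0753 to 0.104), with the same sign for 71.1% of 1069 genes. Both estimates were low, but their intervals are bootstraps over genes and leave out the error between arrays. Replicate 4 of the 1 ppm deficient group, with a 5'/3' ratio of -2.16, also lay below every array of those 4 groups (-1.85 or more). Whether either was the whole cause is therefore not decided. The 6 arrays with high hybridisation controls are 1 per group, so by design a shift that they share cannot make these changes. Within the 18 others the median gene kept 115% (quartiles 108 to 121) of its change and 930 of the calls held. This is no independent test, since these 18 also took part in the calls. With the 5'/3' ratio as a covariate 749 of the calls held, the median gene kept 92.1% of its change and the median SE went from 0.102 to 0.101. The count nevertheless dropped to 80 with tissue scores as covariates, to 161 without the 3 arrays with the lowest 5'/3' ratios and to 190 without replicate 4 of the unexposed group. In the first 2 cases the median gene kept 88.4% (quartiles 77.8 to 99.5) and 93.7% (77.5 to 110) of its change while the median SE went from 0.102 to 0.116 and 0.121, so smaller changes and a wider error both went with the lost calls. No test told their shares apart, and RNA integrity and tissue makeup stay open beside an effect of arsenite.

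Cornified envelope genes were lower at 10 ppm in both diets, by -0.453 in 8 against 8 arrays (exact permutation p = 0.000155, and 0.00125 when arrays were exchanged only within a diet and with the 6 arrays even between the sides). With an estimated correlation the list passed over both diets (adjusted p = 0.0476), but not with the 6 arrays as a block (0.124), with tissue scores as covariates (0.314) or on the deficient diet alone (0.969). A smaller share of epidermis as the whole cause was argued against by the change of the cornified minus the basal keratinocyte mean of -0.266 (exact permutation p = 0.00482, and 0.005 within diet and with the 6 arrays even), though the basal list also fell by 0.187 (exact permutation p = 0.000155), with Krt5 (-0.17, exact p = 0.00466) and Krt14 (-0.07, exact p = 0.0289), so a smaller share may be part of it. RNA integrity predicted a median 0.0132 (0.00624 to 0.0227, bootstrap over genes) of the fall of the 26 called members, an interval that leaves out the error between arrays. An effect of arsenite on cornification stays a hypothesis, found and tested on the same data.

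Other splits of the same arrays were counted to ask whether chance could give as many genes. For 10 ppm on the sufficient diet 1 of 35 splits, the real one, gave as many as 106 (highest other 4), for 10 ppm on the deficient diet 1 of 35 gave 347 (highest other 1), for 1 ppm on the deficient diet 1 of 35 gave 1075 (highest other 1), and for the diets at 1 ppm 1 of 35 gave 58 (highest other 12). Over both diets, 1 of 100 drawn splits gave 682 at 10 ppm (highest other 42) and 1 of 100 gave 216 at 1 ppm (highest other 108). For the diet over all doses 3 of 100 gave 8 or more (highest other 11), and for the interaction at 1 ppm 2 of 100 gave 3 or more (highest other 6). All these 8 shares, with the real split counted in, lay under 0.05. For the interaction the splits exchange doses within a diet and so remove the effect of arsenite as well. They therefore cannot exclude chance for its 3 genes. The splits also mix the 6 arrays with high hybridisation controls, and those with 42, 108 and 11 genes had all of the 6 that were compared on the same side. With these arrays kept even between the sides, only 20 splits of 2 groups exist, too few for a share under 0.05, and the highest other counts were 4 beside 106, 0 beside 347, 0 beside 1075 and 12 beside 58. For the other 4 counts 100 such splits were drawn. Of these, 1 gave 682 or more (highest other 39) and 1 gave 216 or more (highest other 68). Each was the real split, a share under 0.05. For the diet 2 gave 8 or more (highest other 35), and for the interaction 2 gave 3 or more (highest other 21). In each case 1 of the 2 was the real split and the other held more genes. The draws were 100 of 32000 and of 800 possible splits, so chance is not excluded for these 2 counts. The interaction splits with 21 and, at 10 ppm, 106 genes may hold arsenite's effect. The diet's 35 stay unexplained. For counts of 0 the splits decide nothing, since every split gives at least 0, so 35 of 35 counted for 1 ppm on the sufficient diet (highest other 191), for the diets at 0 ppm (highest other 0) and at 10 ppm (highest other 3), and 100 of 100 for the interaction at 10 ppm (highest other 0). The split with 191 genes exchanged replicate 2 of the unexposed and 1 ppm sufficient groups, which points to a structure of these samples, and whether the 2 were exchanged stays open.

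For the number of shifted lists chance was not excluded in any comparison. At 10 ppm, 2 of 35 splits gave 13 or more lists on the sufficient diet (highest other 17) and 13 of 35 gave 5 or more on the deficient diet (highest other 10). At 1 ppm, 14 of 35 gave 10 or more on the sufficient diet (highest other 15) and 17 of 35 gave 6 or more on the deficient diet (highest other 12). Over both diets, 11 of 100 gave 12 or more at 10 ppm (highest other 15) and 11 of 100 gave 11 or more at 1 ppm (highest other 13). Between the diets, 19 of 35 gave 4 or more at 0 ppm (highest other 10), 25 of 35 gave 4 or more at 1 ppm (highest other 13), 27 of 35 gave 5 or more at 10 ppm (highest other 12) and 66 of 100 gave 4 or more over all doses (highest other 14). For the interaction, 49 of 100 gave 7 or more at 10 ppm (highest other 14) and 94 of 100 gave 1 or more at 1 ppm (highest other 14).

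The change with arsenite differed between the diets, by the interaction test, for 3 genes and 8 list results, none of the latter past the test with an estimated correlation. Chance was not excluded for the number of genes or of lists. At 1 ppm the differences were -0.826 for Bcat2, -0.826 for Cd82, -0.673 for Pla2g2e and a list median of 0.293 for hyperproliferative epidermis (adjusted p = 0.904 with an estimated correlation). At 10 ppm the list medians were 0.0582 for heat shock proteins, 0.0911 for the cornified envelope, 0.188 for hyperproliferative epidermis, -0.287 for myeloid cells, -0.131 for fibroblast and matrix, -0.312 for the interferon response and -0.313 for immediate early genes. Among 2941 probe sets with no single gene, which the comparisons do not use, 17 changed at 10 ppm over both diets, 4 higher and 13 lower.

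Single arrays far from the others of their group are given with the gap to the nearest other array as a share of the group's range. In the unexposed sufficient group, replicate 1 lay above the other 3 for Aldh1l2 (0.91), Pecam1 (0.855), Slc30a1 (0.832), the upper quartile (0.831) and the endothelium list (0.947) and below the other 3 for Mt1 (0.881). Replicate 2 lay above the other 3 for G0s2 (0.832), Gbp2 (0.833) and the interferon response list (0.92) and below the other 3 for Cth (0.831), Lce3a (0.927) and the 5'/3' ratio (0.848). Replicate 3 lay above the other 3 for Il1f6 (0.94) and Ube2c (0.837) and below the other 3 for Mt4 (0.885). Replicate 4 lay above the other 3 for Apoa2 (0.895) and Serpina1b (0.843) and below the other 3 for Clec4b1 (0.947) and the ribosomal proteins list (0.896). In the 1 ppm sufficient group, replicate 1 lay above the other 3 for Alox12b (0.85), the hybridisation controls (0.871), the basal keratinocyte list (0.83), the DNA repair list (0.869) and the DNA and histone methylation list (0.87). Replicate 2 lay above the other 3 for Hoxa9 (0.857) and below the other 3 for Cd68 (0.963), Fn1 (0.833) and Mcpt4 (0.868). Replicate 4 lay below the other 3 for Cxcl10 (0.85). In the 10 ppm sufficient group, replicate 1 lay below the other 3 for Mcpt4 (0.868) and the mast cell list (0.881). Replicate 2 lay above the other 3 for Clec4b1 (0.842) and Mrc1 (0.901) and below the other 3 for Krt16 (0.906) and Mthfd2 (0.833). Replicate 4 lay above the other 3 for Col17a1 (0.927), Fosb (0.9) and Ttk (0.863) and below the other 3 for Nr1d1 (0.957). In the unexposed deficient group, replicate 1 lay above the other 3 for Ms4a2 (0.886). Replicate 2 lay above the other 3 for Hoxc13 (0.85) and below the other 3 for H2-Aa (0.871) and the adipocyte list (0.841). Replicate 3 lay above the other 3 for Serpina1c (0.832). Replicate 4 lay above the other 3 for Tap1 (0.865) and below the other 3 for Aspn (0.83), Cd209a (0.916), Gjb6 (0.865), Mat2b (0.862), Me1 (0.917) and Mrpl50 (0.937). In the 1 ppm deficient group, replicate 1 lay above the other 3 for Sprr2d (0.924), Ttk (0.888) and the DNA repair list (0.89) and below the other 3 for Krt32 (0.933). Replicate 2 lay above the other 3 for Ms4a2 (0.894) and below the other 3 for Krt6b (0.901). In the 10 ppm deficient group, replicate 2 lay above the other 3 for the endothelium list (0.911) and below the other 3 for Chordc1 (0.83). Replicate 3 lay above the other 3 for Alox12b (0.906) and Shmt1 (0.913). Replicate 4 lay above the other 3 for Sardh (0.964) and below the other 3 for Irgm1 (0.836), Lce1l (0.917), Loxl1 (0.864), Map3k8 (0.899), Vwf (0.861) and the inflammatory list (0.871). Replicate 4 of the unexposed and of the 10 ppm deficient group held 7 of these each, and replicates 1 and 2 of the unexposed sufficient group 6 each.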

How the results depend on the processing

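The block for the 6 arrays, the 18 others alone, the 5'/3' covariate, the fit with no pseudocount and both sets of left-out arrays were chosen only after the result was seen. Of 12811 refits of 531 named gene values 34 reversed, 0 among the 195 called, a test with little room to fail. The covariate for sex was not run, since all arrays showed 1 sex, and the mean diet contrast holds all 6 groups, so it has no value with only the compared groups. The number of arrays and the signal over background limit what can be seen, and the cause was not tested unless it is given.

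The replicate number as a block gave 14 genes for the diets at 1 ppm and 5 for the diet over all doses. For the other comparisons the counts of genes with the block were 77 and 0 at 10 and 1 ppm on the sufficient diet, 238 and 1074 at 10 and 1 ppm on the deficient diet, 659 and 149 at 10 and 1 ppm over both diets, 0 and 3 for the interactions at 10 and 1 ppm and 0 for the diets at 0 and at 10 ppm. The counts of lists with the block were 5 against 6 at 1 ppm on the deficient diet and 3 against 4 for the diets at 0 ppm, and those of the other comparisons stayed the same. The numbers as a whole showed no steady pairing of the mice. Of 28 pairs with the same number, 14 had a correlation over 0.1, and in 0 comparisons every pair had. Correlations ran from -0.664 to 0.664, and 8 of 24 arrays matched best with their own number outside the group. Where both arrays of a replicate 1 pair were among the 6 with high hybridisation controls, the correlation was 0.330 to 0.512. For replicate 1 pairs with the 10 ppm deficient group it was -0.260 and -0.664. Number 1 thus went with those 6 arrays, and pairing of the mice is not excluded.

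Without the filter on dim genes, 7 lists shifted for the diets at 0 ppm and 6 for the interaction at 1 ppm. With all probe sets, where more features were tested, the counts were 36 genes at 10 ppm on the sufficient diet, 68 at 1 ppm over both diets and 34 for the diets at 1 ppm, with 8 lists for the diets at 0 ppm, 9 for the diets at 1 ppm, 11 for the interaction at 10 ppm and 9 for the interaction at 1 ppm. After quantile normalization 1 gene and 6 lists passed for the interaction at 1 ppm. With no pseudocount 2 lists passed for the interaction at 1 ppm.

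Array weights gave 785 and 695 genes at 10 and 1 ppm on the sufficient diet, 1194 at 10 ppm on the deficient diet, 2364 and 2039 at 10 and 1 ppm over both diets, 54 and 416 for the diets at 0 and 1 ppm, 352 for the diet over all doses, and 4 and 78 for the interactions at 10 and 1 ppm. They gave 10 lists at 10 ppm and 10 at 1 ppm on the deficient diet, 2 for the diets at 0 ppm and 6 for the interaction at 1 ppm.

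Tissue scores as covariates gave 653 and 80 genes at 10 and 1 ppm on the deficient diet, 0 at 1 ppm over both diets, 15 for the diets at 1 ppm, 14 for the diet over all doses and 1 for the interaction at 10 ppm. They gave 3 lists at 10 ppm and 3 at 1 ppm on the deficient diet, 5 at 1 ppm on the sufficient diet, 4 at 1 ppm over both diets, 7 and 2 for the diets at 0 and 1 ppm and 2 for the interaction at 1 ppm. With only the compared groups in the fit, which leaves fewer arrays to set the spread, 1 and 3 genes passed at 10 and 1 ppm on the deficient diet and 0 for the diets at 1 ppm and for the interaction at 1 ppm, with 7 lists for the diets at 0 ppm and 5 for the interaction at 1 ppm.

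The 6 arrays as a block gave 164 genes at 10 ppm on the sufficient diet, 734 and 1728 at 10 and 1 ppm on the deficient diet, 1107 and 534 at 10 and 1 ppm over both diets, 119 for the diets at 1 ppm, 14 for the diet over all doses and 18 for the interaction at 1 ppm. The 18 others alone gave 41 and 1 genes at 10 and 1 ppm on the sufficient diet, 1 and 32 for the diets at 0 and 1 ppm, 0 for the diet over all doses and 0 for the interaction at 1 ppm, with 3 lists at 10 ppm on the deficient diet, 1 for the diets at 0 ppm, 2 for the diet over all doses and 3 for the interaction at 1 ppm. The 5'/3' covariate gave 771 genes at 10 ppm on the deficient diet, 1069 at 10 ppm over both diets, 88 for the diets at 1 ppm, 22 for the diet over all doses and 28 for the interaction at 1 ppm, with 3 lists at 1 ppm on the deficient diet and 2 for the interaction at 1 ppm.

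Without the 2 arrays of lowest weight, 39 and 367 genes passed at 10 and 1 ppm on the deficient diet, 107 at 1 ppm over both diets, 140 for the diets at 1 ppm and 13 for the diet over all doses, with 12 lists at 10 ppm on the deficient diet, 7 for the diets at 0 ppm and 5 for the interaction at 1 ppm. Without the 3 arrays with the lowest 5'/3' ratios, 177 and 161 genes passed at 10 and 1 ppm on the deficient diet, 0 at 1 ppm over both diets, 0 for the diets at 1 ppm, 5 for the diet over all doses and 1 for the interaction at 1 ppm, with 0 lists for the interaction at 1 ppm.

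Leaving out each array in turn moved the counts of genes between 11 and 79 at 10 ppm and 0 and 35 at 1 ppm on the sufficient diet, 86 and 402 at 10 ppm and 190 and 1255 at 1 ppm on the deficient diet, 422 and 799 at 10 ppm and 47 and 575 at 1 ppm over both diets, 0 and 152 for the diets at 1 ppm, 5 and 17 for the diet over all doses and 1 and 8 for the interaction at 1 ppm. The counts of lists lay between 3 and 8 at 10 ppm and 3 and 9 at 1 ppm on the deficient diet, 0 and 7, 3 and 7 and 3 and 7 for the diets at 0, 1 and 10 ppm, and 1 and 5 for the interaction at 1 ppm.

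The reversed values belong to genes near 0 without a call. For 10 ppm over both diets Mt1 was -0.00223 after quantile normalization, -0.0473 with array weights, -0.0300 on the 18 arrays, -0.00673 with the 5'/3' covariate, -0.00759 without the 2 arrays of lowest weight, -0.0144 without the 3 arrays with the lowest 5'/3' ratios, and between -0.0488 and 0.0421 without 1 array. Krt6a was -0.0159 with array weights, -0.0242 without the 2 arrays of lowest weight, and between -0.0190 and 0.0284 without 1 array. Krt6b lay between -0.0633 and 0.202 and Hmox1 between -1.85e-06 and 0.157 without 1 array, and Nqo1 was 0.0330 with array weights. For 1 ppm over both diets Mt1 was 0.0116 with array weights and between -0.0755 and 0.00414 without 1 array, and Krt6a was 0.0231 with tissue scores. Slc39a14 at 1 ppm on the sufficient diet was -0.0185 with tissue scores, and As3mt over all doses was -0.00263 on the 18 arrays and between -0.0283 and 0.0354 without 1 array.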

Other observations

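The clock score of Nr1d1 was devised and tested only after the result was seen.

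The mean level of the mast cell list, which rests on 9 genes, was higher at both doses, but the list was not called at 10 ppm on the deficient diet (camera adjusted p = 0.135). Relative to the unexposed sufficient group, the list averaged 0.47 ± 0.32 (SD, n = 4) at 1 ppm and 0.26 ± 0.31 (SD, n = 4) at 10 ppm on the sufficient diet, and 0.03 ± 0.09 (SD, n = 4) at 0 ppm, 0.41 ± 0.28 (SD, n = 4) at 1 ppm and 0.18 ± 0.14 (SD, n = 4) at 10 ppm on the deficient diet. With an estimated correlation between genes none of its calls held (adjusted p = 0.192 at 1 ppm on the sufficient diet and 0.986 on the deficient diet).

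Skeletal muscle genes varied between the mice of a group, most at 1 ppm. Relative to the unexposed sufficient group, the list averaged -1.03 ± 1.03 (SD, n = 4) at 1 ppm and 0.12 ± 0.47 (SD, n = 4) at 10 ppm on the sufficient diet, and 0.23 ± 0.31 (SD, n = 4), -0.42 ± 0.84 (SD, n = 4) and 0.09 ± 0.58 (SD, n = 4) at 0, 1 and 10 ppm on the deficient diet.

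Nr1d1, a repressor of the circadian clock, was lower on the deficient diet over all doses, though hardly in unexposed mice (-0.10 ± 0.11, limma adjusted p = 0.834), and another phase of the circadian clock at sampling may account for it. If so, genes in phase with Nr1d1 would be lower and genes in antiphase higher. The difference of the 2 means was -0.265 between 12 deficient and 12 sufficient mice (SD 0.251 and 0.151, permutation p = 0.0046, two-sided). Of the members, Dbp (-0.36, adjusted p = 0.126), Cry1 (0.37, adjusted p = 0.135), Nfil3 (0.19, adjusted p = 0.248) and Nr1d2 (-0.18, adjusted p = 0.409) had the smallest p-values, and none was past limma's threshold. Per3 (-0.13) and Ciart (-0.07) went the same way as Nr1d1 by less, Tef (-0.02), Arntl (0.03) and Clock (-0.00166) barely differed, and Hlf (0.04) went against the prediction, as did Clock in sign. The time of sampling of each mouse is not given in the sources used here, so an effect of the diet on the clock and a difference in sampling time stay open.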
